A study of Mus musculus with 20 samples.

How the data were processed

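The data are bulk RNA-seq libraries of 20 mouse nerve tumors: 12 neurofibroma, 4 paraspinal tumor (2 of subgroup 1 and 2 of subgroup 2) and 4 GEM-PNST libraries. Per the labels, total RNA was extracted with the RNeasy Plus Micro Kit and libraries were made with the Nextera XT kit. The deposited table holds raw counts of reads per gene, which the authors made from reads aligned to mm10. Per the labels' processing notes TopHat, HISAT2 and featureCounts were used, but the notes give no version or role for any of them and do not say which aligner served which libraries. The annotation and the strand setting are not stated. The counts were tested to be whole numbers of 0 or more in all 20 columns.

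Each library was matched to its group by the table that pairs sample names with alignment files. Those file names place neurofibroma libraries 1 to 6 in 1 sequencing run, neurofibroma libraries 7 to 12 in another, and all paraspinal and GEM-PNST libraries in the run they share. No fit with run as a term can be made for a comparison with neurofibroma, so run and stage cannot be told apart there. The labels do not say that each library came from a separate animal, and the codes of neurofibroma libraries 8 and 9 share a number. The codes of paraspinal subgroup 1 library 1 and GEM-PNST library 2 also differ only in their last letter and letter case, but these libraries differ in Xist (4 and 4556 counts) and Ddx3y (840 and 0 counts), transcripts that mark sex. The p-values therefore measure the spread between samples. A comparison of 74 pairs of libraries within groups found no pair with counts alike enough to be the same library (lowest chi-square per degree of freedom 23.88). Pairs across groups were not compared in this way.

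Genes were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests on counts with TMM factors, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Adjusted p-values of single genes come from edgeR unless another tool is named, and those of lists from limma 3.58.1. Of 24062 genes, 16589 passed edgeR's expression filter over all libraries, and they held 95.78% to 99.97% of each library's counts. Each stage comparison used only the libraries of its stages, and the subgroup comparison was fitted with the GEM-PNST libraries to share their spread. CPM are counts scaled by library total and TMM factor, and log2 CPM use a prior count of 2. The stricter filter, the 5 CPM minimum for genes at 0 counts elsewhere and genes outside the tested set use CPM scaled by library total alone. The standard error of a log2 fold change was computed from its size and F value. A fold against a group with 0 counts was bounded with a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval was given. A floor of 3 counts lay below 1 CPM in every library.

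The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named were the targeted genes, up to 10 genes each way per comparison with the largest change among those past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups, and up to 4 members per list, or 2 where no member passed. From these a selection was printed. For the 38 lists, camera was run with a preset correlation of 0.01 and with an estimated correlation, beside fry, and members were also counted when adjusted over the list alone. Gene positions come from the GENCODE annotation of GRCm38, which shares its coordinates with mm10. Genes with near-identical copies, such as keratin, MHC class II and olfactory or vomeronasal receptor genes, are uncertain where the counting could split their reads. Overlapping and antisense genes are uncertain too, since the counting is not stated to use strand.

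Alternatives were RLE factors, no filter, a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom with sample weights, all 20 libraries in 1 fit, a 2-fold minimum, each paraspinal subgroup alone, the replicate number as a block and each paraspinal and GEM-PNST library left out in turn. Neurofibroma libraries 8 and 9 were also left out in turn. Chosen after seeing the data were fits without GEM-PNST libraries 1 and 3, without neurofibroma library 4, without Rn45s and Malat1, with a trend over gene length and GC content removed, and with each neurofibroma run alone. The replicate numbers come from the sample titles, and whether they pair the samples was not decided. Overlaps between comparisons were set beside 20 simulations of unchanged groups against shared controls. Groups and controls were all simulated, from the means and spread of the neurofibroma libraries.

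The tests were tried on simulated data with 200 changed genes, after the data were examined. Of 100 genes changed 2-fold and 100 changed 4-fold, 49 and 88 were recovered for paraspinal against neurofibroma, 0 and 1 for GEM-PNST against paraspinal, 26 and 74 for GEM-PNST against neurofibroma, and 0 and 0 between the subgroups. False calls numbered 2, 0, 3 and 0.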

Results

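RNA from mouse nerve tumors of 3 stages was sequenced in 20 libraries, and the deposited table gives read counts for 24062 genes in each of them. The stages were neurofibroma (12 libraries), paraspinal tumor (4 libraries) and GEM-PNST (4 libraries), the labels' name for peripheral nerve sheath tumors of genetically engineered mice. Neurofibromas came from mice in which DhhCre, a recombinase active in the Schwann cell lineage, removes floxed Nf1. The paraspinal and GEM-PNST mice also carried 1 disrupted copy of the Ink4a/Arf locus. The labels divide the paraspinal tumors into subgroup 1 (2 libraries) and subgroup 2 (2 libraries) and call these sub-clusters, so the subgroups may have been drawn from these expression values. Total counts ranged from 9900759 to 17594164 in neurofibroma, 18474071 to 24314222 in paraspinal and 16282605 to 22218382 in GEM-PNST libraries. All paraspinal and GEM-PNST libraries came from 1 sequencing run and the neurofibroma libraries from another 2, so run and stage cannot be told apart in any comparison with neurofibroma. The disrupted Ink4a/Arf copy divides the libraries in the same way, so genotype cannot be told apart from stage there either.

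The genes that the mouse lines target were read first, in every library. Nf1, a brake on RAS signaling, had 248.5 ± 19.8 CPM (mean ± SD, n = 12) in neurofibroma, 63.6 ± 29.3 CPM (n = 4) in paraspinal and 26.3 ± 3.39 CPM (n = 4) in GEM-PNST libraries. Cdkn2a, the Ink4a/Arf gene and a cell cycle inhibitor, had 0.485 ± 0.401 CPM (n = 12) in neurofibroma and 19.9 ± 12.1 CPM (n = 4) in paraspinal libraries. In GEM-PNST libraries 1 to 4 it had 5.56, 0.541, 7.06 and 9.88 CPM. Its neighbor Cdkn2b, another cell cycle inhibitor, had 30.6, 2.92, 51.4 and 73.7 CPM in the same libraries, so both were lowest in library 2. On GRCm38, Nf1 lies on chromosome 11 (79339693 to 79581612), Cdkn2a on chromosome 4 (89274471 to 89294653) and Cdkn2b on chromosome 4 (89306299 to 89311039). A count over a whole gene includes reads from outside a floxed or disrupted part and from cells without the recombinase, so these values do not check the deletions.

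**Figure D1:**
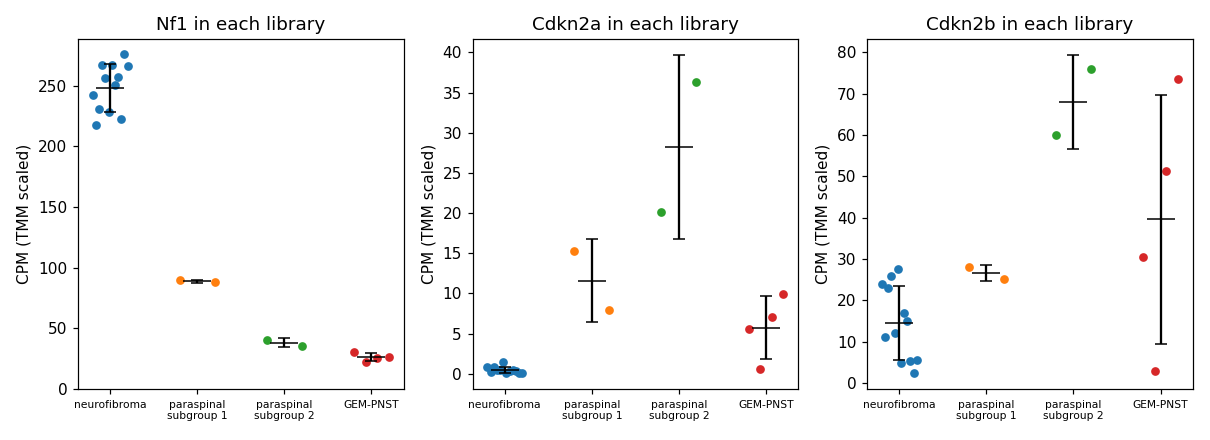
Normalized read counts (CPM) of Nf1, Cdkn2a and Cdkn2b in each library, with the mean and SD of each group. Nf1 sits between 217.55 and 275.94 CPM in the 12 neurofibroma libraries and between 22.506 and 30.715 CPM in the 4 GEM-PNST libraries.

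GEM-PNST and paraspinal tumors share a genotype label and a sequencing run, so they were compared first. Transcripts of sensory neurons, of myelinating Schwann cells and of sterol synthesis fell from paraspinal to GEM-PNST libraries as lists by camera, and those of the cell cycle rose. None of these lists passed with an estimated correlation (adjusted p of 0.213, 0.564 and 0.213, and 0.636 for both cell cycle lists). Fry tests whether members move on balance 1 way, and not against other genes. By it all of these lists passed (adjusted p of 3.4e-05, 0.00306 and 0.000305, and 0.0257 and 0.0341 for S and for G2 and M phase). In this comparison 13 of the 38 lists passed by fry. Scn10a, a sodium channel of pain-sensing neurons (chromosome 9, 119608456 to 119719322), had 235.8 ± 181.9 CPM (n = 4) in paraspinal libraries and 0 counts in all 4 GEM-PNST libraries, at least 5052-fold lower with a floor of 3 counts over the group. Floors and counting intervals cover counting error only. Ugt8a, which makes the myelin lipid galactosylceramide (chromosome 3, 125865271 to 125938619), fell by 10.07 on the log2 scale (SE 1.2, adjusted p = 0.00346). Sqle, an enzyme of cholesterol synthesis (chromosome 15, 59315077 to 59331192), fell by 2.28 (SE 0.24, adjusted p = 0.00202). Krt18, an epithelial keratin (chromosome 15, 102028180 to 102032027), had 3 counts over the paraspinal and 10758 over the GEM-PNST libraries, a ratio of 5170 (95% counting interval 1770 to 25100).

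Of 16589 genes tested, 1686 (10.2%) passed the threshold between GEM-PNST and paraspinal libraries, 411 higher and 1275 lower in GEM-PNST. Among them 180 had no count in any GEM-PNST library. Over all genes tested, called or not, every library of 1 stage lay above every library of the other in 4582 (27.6%), which chance gives for 2.86% of genes. The count was 525 and 507 without subgroup 1 library 1 or 2, 1104 and 783 without subgroup 2 library 1 or 2, 708 without GEM-PNST library 4, and 2304 without GEM-PNST library 3. In the same order, the genes higher in GEM-PNST numbered 19 and 23, 199 and 42, 82, and 652. The count of all genes called was 4711 by DESeq2, 2714 by limma-voom, 6631 with all 20 libraries in 1 fit (49.8% higher in GEM-PNST, against 24.4%), and 61, all lower, against subgroup 2 alone. Of the single genes followed over the settings 73 passed in the main fit, and 66 lost the call against subgroup 2 alone. In simulated data with 200 changed genes the test recovered 1% of genes changed 4-fold. The adjusted threshold is easier to pass where more genes change, so this share may not hold for the real libraries.

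The sensory neuron list fell furthest of the 38 lists fixed before the data were examined. Of its 30 measured members 25 fell and none rose, 27 fell when adjusted over the list alone, and the median log2 fold change was -7.03. Pou4f1, a transcription factor of sensory neurons, had 3 counts over the GEM-PNST libraries, a ratio of 851 (95% counting interval 291 to 4130) in favor of paraspinal. Rbfox3, a splicing factor of mature neurons, fell by 6.95 (SE 0.45), and Stmn3, a neuronal microtubule regulator, fell by 12.10 (SE 0.99). Among the genes with the largest decreases, Rph3a, a synaptic vesicle protein, was at least 2899-fold lower, Rab3c, a vesicle GTPase, at least 2410-fold lower, and Prdm12, a regulator of pain-sensing neurons, at least 1052-fold lower, each with 0 counts in all 4 GEM-PNST libraries. Every gene said to rise or fall between these stages had all GEM-PNST libraries on 1 side of all paraspinal libraries. The list's adjusted p was 1.78e-19 by camera, and adjusted p = 0.213 with an estimated correlation. Its mean could also differ widely within a stage: it was 1.15 log2 CPM in neurofibroma library 4, against 6.2 to 8.63 in the other neurofibroma libraries. Whether ganglion tissue in the dissections carried the neuronal transcripts was not tested.

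Myelinating Schwann cell transcripts fell with the neuronal ones. Of 19 members 12 fell, 15 when adjusted over the list alone, with a median of -5.42 and a camera adjusted p of 1.04e-10 (adjusted p = 0.564 with an estimated correlation). Pmp22, a myelin membrane protein, fell by 4.64 (SE 0.75) and Cldn19, a tight junction protein of myelin, fell by 8.42 (SE 1.42). In the Schwann cell lineage list 2 of 19 members fell, also when adjusted over the list alone, with a median of -3.04 and a camera adjusted p of 7.6e-06 (adjusted p = 0.741 with an estimated correlation). Fabp7, a fatty acid carrier of immature glia, fell by 6.46 (SE 1.19, adjusted p = 0.0161, 0.0523 without GEM-PNST library 4, and 0.0537 and 0.164 with subgroup 1 or 2 alone). Sox10, the transcription factor that sets Schwann cell identity, had 0.61, 0.487, 438.4 and 5.67 CPM in GEM-PNST libraries 1 to 4 against 396.8 ± 65.1 CPM (n = 4) in paraspinal libraries. Its log2 fold change was -1.86 (SE 1.80, adjusted p = 0.5), with an adjusted p of 0.00828 without GEM-PNST library 3.

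Lists of other nerve cells and of WNT and hedgehog signaling also had negative medians and passed by camera. In the immature and repair Schwann cell list 3 of 19 members fell, also when adjusted over the list alone (median -1.59, camera adjusted p = 0.00429; adjusted p = 0.741 with an estimated correlation), among them Shh, a hedgehog ligand, at least 581-fold lower, and Ncan, a matrix proteoglycan, at least 87.9-fold lower. In the perineurial list 5 of 17 members fell, 8 when adjusted over the list alone (median -2.87, camera adjusted p = 0.000428; adjusted p = 0.564 with an estimated correlation), and Sgpp2, a sphingosine phosphate phosphatase, fell by 9.05 (SE 0.98). In the satellite and central glia list 5 of 11 members fell, 6 when adjusted over the list alone, with a median of -3.66, or -3.53 with its member at 0 counts set to its bound. Its camera adjusted p was 0.0173, and 0.0748 without GEM-PNST library 1 (adjusted p = 0.564 with an estimated correlation). In the WNT and hedgehog list 6 of 20 members fell, also when adjusted over the list alone, with a median of -1.2 and a camera adjusted p of 0.015, or 0.0875 without GEM-PNST library 1 (adjusted p = 0.741 with an estimated correlation). Wnt6, a WNT ligand, fell by 4.06 (SE 0.71). Col9a2, a collagen of cartilage, fell by 8.78 (SE 0.72). Its list of cartilage and bone genes did not pass (camera adjusted p = 0.165) and went both ways, with a median of 0.4, 3 of 10 members lower, and 1 higher and 3 lower when adjusted over the list alone.

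Transcripts of sterol and lipid synthesis fell as well. Of 21 members 16 fell, 19 when adjusted over the list alone, with a median of -1.8 and a camera adjusted p of 1.74e-09 (adjusted p = 0.213 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell by 3.70 (SE 0.52). The mean log2 CPM of the list was 6.98 ± 0.34 (SD, n = 4) in paraspinal and 5.07 ± 0.13 (n = 4) in GEM-PNST libraries. Among neurofibroma libraries it was lowest in library 4 (6.05) and highest in library 11 (7.58). These were also the lowest and highest for the sensory neuron list (1.15 and 8.63). Whether ganglion tissue in the dissections carried the sterol transcripts was not tested.

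Cell cycle transcripts rose in GEM-PNST libraries. In the S phase list 8 of 30 members rose, 24 when adjusted over the list alone, with a median of 1.73 and a camera adjusted p of 5.68e-12 (adjusted p = 0.636 with an estimated correlation). In the G2 and M phase list 4 of 32 members rose, 31 when adjusted over the list alone, with a median of 2.2 and a camera adjusted p of 2.94e-13 (adjusted p = 0.636 with an estimated correlation). The mean log2 CPM of the G2 and M phase list was 2.65 ± 1.25 (SD, n = 4) in paraspinal and 5.28 ± 0.62 (n = 4) in GEM-PNST libraries. Cdt1, which licenses replication origins, rose by 2.62 (SE 0.50, adjusted p = 0.0188), a call lost without subgroup 1 library 1 (0.0619) or 2 (0.0658) or subgroup 2 library 2 (0.0559). Mki67, a marker of cycling cells, had a log2 fold change of 1.99 (adjusted p = 0.0642), and passed by DESeq2 (0.00839), by limma-voom (0.0312), with all 20 libraries in 1 fit (0.0255) and without subgroup 2 library 1 (0.0411). The cell cycle inhibitors had log2 fold changes of -1.83 (SE 0.81, adjusted p = 0.157) for Cdkn2a and -1.25 (SE 0.40, adjusted p = 0.0775) for Cdkn1a. Cdkn1a passed by DESeq2 (0.018), by limma-voom (0.0256), with all 20 libraries (0.02), with the length and GC trend removed (0.048) and without GEM-PNST library 2 (0.0329). Nf1 had -1.36 (SE 0.36, adjusted p = 0.0502), and passed by DESeq2 (0.00528), with all 20 libraries (0.000667), with a stricter filter (0.0493), without Rn45s and Malat1 (0.0484), with subgroup 1 alone (0.0245) and without subgroup 2 library 2 (0.0477).

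The immune lists differed among themselves. The mast cell and neutrophil lists had medians of -0.52 and -0.81 and no member past the threshold, alone or over all genes. The T and NK cell list had 2 of 18 members higher, 6 when adjusted over the list alone, with a median of 4.02 and a camera adjusted p of 0.000529 (adjusted p = 0.846 with an estimated correlation). Its list mean was 0.51, -1.8, 4.11 and 2.11 log2 CPM in GEM-PNST libraries 1 to 4 and ranged from -1.79 to -0.51 over the paraspinal ones, so library 2 lay no higher than these. The paraspinal means lay below 1 CPM, near the floor, so the size of this difference is uncertain. Library 3, the highest, was also the library in which 16 of 19 measured salivary gland genes were highest, and without it the camera adjusted p was 0.0151. The macrophage list had 1 of 24 members higher and 0 when adjusted over the list alone, with a median of 1.41 and a camera adjusted p of 0.00115 (adjusted p = 0.817 with an estimated correlation). The dendritic cell and MHC class II list had 0 of 15 members higher over all genes and 9 when adjusted over the list alone. Its camera adjusted p was 0.0283, and 0.88 with an estimated correlation. That call was lost without subgroup 1 library 2 (0.0691), GEM-PNST library 1 (0.164) or GEM-PNST library 3 (0.135). In the mitochondrial respiration list no member passed, alone or over all genes, while the camera adjusted p was 0.015 (median 0.47; adjusted p = 0.88 with an estimated correlation), and the call was lost without subgroup 1 library 1 (0.0674) or GEM-PNST library 1 (0.111). By fry the T and NK cell (0.295), macrophage (0.246), dendritic cell and MHC class II (0.51) and mitochondrial (0.466) lists did not pass.

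Genes outside the lists also rose. Krt8, the partner keratin of Krt18, rose by 11.68 (SE 2.74, adjusted p = 0.0363), and the counts of both keratins may include reads shared with their processed pseudogenes. The Krt8 call was lost without subgroup 1 library 1 (0.111) or 2 (0.111), subgroup 2 library 1 (0.0735) or 2 (0.111) or GEM-PNST library 4 (0.0518), and by limma-voom (0.0567). Without GEM-PNST library 4 its log2 fold change was 6.88, and without subgroup 2 library 2 it was 14.82. Glipr1 rose by 4.66 (SE 0.66, adjusted p = 0.00659). The other 24 lists had camera adjusted p from 0.0547 to 0.981. In the neural crest, fibroblast, skeletal muscle, cartilage and bone, adipocyte, red blood cell, endothelial, ERK output, growth factor and cell cycle inhibitor lists the median, the mean or the test differed in sign.

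**Figure D2:**
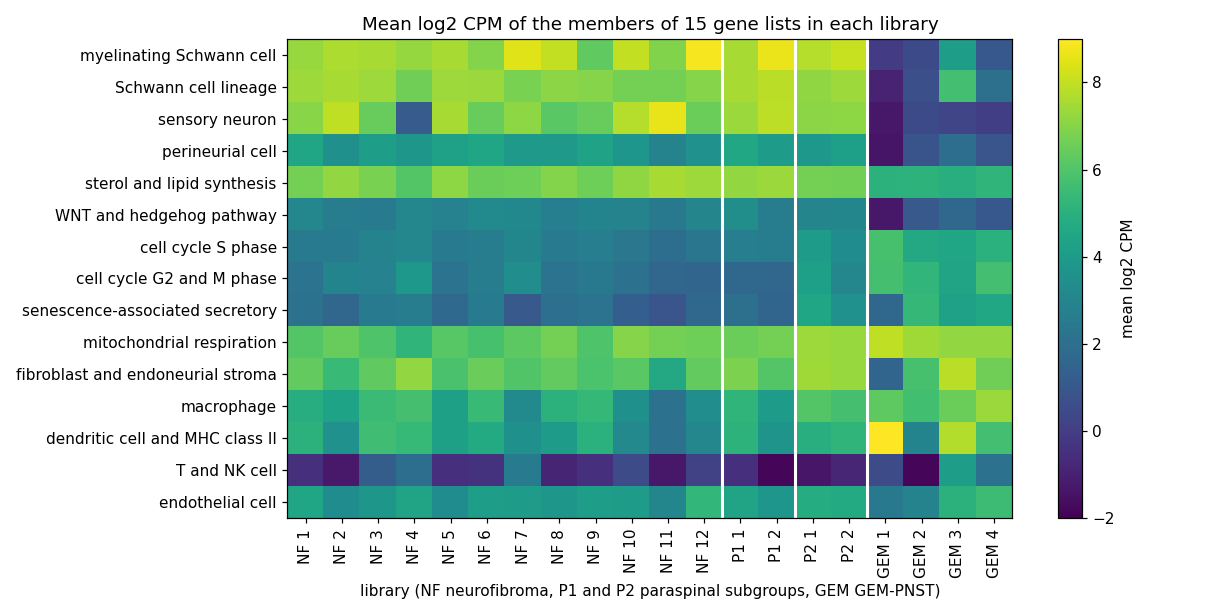
Mean log2 CPM of the members of fixed gene lists in each library, with the libraries ordered by group. The sensory neuron list lies between 7.1 and 7.92 in the 4 paraspinal libraries and between -1.31 and 0.48 in the 4 GEM-PNST libraries.

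Paraspinal and neurofibroma libraries differed in single genes such as Cdkn2a, Nf1, Junb and Bax, with run, genotype and stage confounded throughout. Cdkn2a was higher in paraspinal libraries by 5.31 on the log2 scale (SE 0.49, adjusted p = 9.98e-08) and Cdkn2b by 1.71 (adjusted p = 0.00633), a call lost with subgroup 1 alone (0.296) and after the removal of a trend over gene length and GC content (0.243). Nf1 fell by 1.97 (SE 0.23, adjusted p = 1.05e-06). Junb, an early response transcription factor, rose by 4.15 (SE 0.34), and Bax, which promotes cell death, rose by 2.79 (SE 0.26).

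In this comparison 9858 genes (59.4%) passed the threshold, 5008 higher and 4850 lower in paraspinal. Over all genes tested, called or not, the stages did not overlap in 6057 (36.5%), which chance gives for 0.11% of genes. No list passed by camera, where the lowest adjusted p was 0.129 for mitochondrial respiration (16 of 24 members higher and 2 lower, 18 and 2 when adjusted over the list alone; adjusted p = 0.985 with an estimated correlation). By fry, which compares a list with no change and not with other genes, 4 lists passed, each with adjusted p = 0.985 with an estimated correlation by camera. The homeobox and developmental factors under polycomb had 2 members higher and 6 lower of 15 (median -0.89; fry 5.9e-08, camera 0.556), and immediate early genes had 10 higher and 2 lower of 20 (median 1.17; fry 0.00214, camera 0.28), with the same counts when adjusted over the list alone. RAS regulators went both ways, with 8 higher and 10 lower of 26, also when adjusted over the list alone (median -0.12; fry 0.0177, camera 0.734). Cell cycle inhibitors with p53 targets had 9 higher and 4 lower of 24, and 8 and 4 when adjusted over the list alone (median 0.61; fry 0.0419, camera 0.587).

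Schwann cell genes were present in both stages. Of the myelinating list 6 of 19 members rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.72; adjusted p = 0.985 with an estimated correlation), with Cadm4, an adhesion protein of myelinating Schwann cells, higher by 3.39 (SE 0.30). Sox10 was higher by 1.31 (SE 0.23, adjusted p = 8.55e-05, and 0.226 with all 20 libraries in 1 fit), but its log2 fold change was -0.46 once a trend over gene length and GC content was removed, and that of Foxd3, a neural crest factor, went from 1.54 to -0.59. C1qa, a complement gene of macrophages, rose by 3.65 (SE 0.63) and Cd3d, part of the T cell receptor complex, fell by 3.66 (SE 0.44). Tpsb2, a mast cell tryptase, rose by 2.57 (SE 0.44). Timp1, a metalloproteinase inhibitor, rose by 4.27 (SE 0.88), with -0.05 in subgroup 1 alone and an adjusted p of 0.125 by limma-voom. The stages overlapped for Timp1 and Cdkn2b.

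Some of the largest differences were in genes with 0 counts in every paraspinal library. Olfr613, an olfactory receptor gene, was at least 8715-fold lower and Vmn1r58, a vomeronasal receptor gene, at least 5996-fold lower, each with 0 counts in the paraspinal libraries. In all, 33 genes had at least 5 CPM in every neurofibroma library and 0 counts in all 8 others, 5 of them receptor genes of these families, and 2 genes showed the reverse. No gene did so between the 2 neurofibroma runs. Within the run shared by the other stages, 39 genes had at least 5 CPM in every paraspinal library and 0 counts in all 4 GEM-PNST libraries, and no gene showed the reverse. Genes higher in paraspinal libraries had a median GC content of 54.5%, against 45.1% for genes that were lower, and across 15738 genes, which are not independent replicates, Spearman's rho of the log2 fold change was 0.56 with GC content and -0.28 with exon length. With that trend removed 7387 genes passed, 5452 of them called before in the same direction.

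By camera the sensory neuron, myelinating Schwann cell, Schwann cell lineage and sterol lists were lower in GEM-PNST than in neurofibroma libraries. The cell cycle lists were higher, and the immature and repair Schwann cell list did not pass. Each list that passed had adjusted p = 0.949 with an estimated correlation, and run, genotype and stage were confounded. Nf1 fell by 3.26 (SE 0.14, adjusted p = 2.72e-11). Cdc20, an activator of mitotic exit, rose by 4.71 (SE 0.29) and Fen1, a replication nuclease, by 3.98 (SE 0.28). Ugt8a fell by 11.24 (SE 1.16), and Scn10a was at least 6974-fold lower. Crabp1, a retinoic acid carrier, rose by 9.69 (SE 0.95, adjusted p = 1.4e-07), with 4.54, 2215, 64.3 and 2250 CPM in GEM-PNST libraries 1 to 4.

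In this comparison 12119 genes (73.1%) passed, 5801 higher and 6318 lower in GEM-PNST. Over all genes tested, called or not, the stages did not overlap in 7706 (46.5%), which chance gives for 0.11% of genes. The median log2 fold change over all genes was -0.138. Of the 38 lists 9 passed by camera, all with adjusted p = 0.949 with an estimated correlation, and 20 passed by fry. Higher were S phase (28 of 30 members, 1 lower; 4.6e-08), G2 and M phase (26 of 32, 1 lower; 3.8e-07) and mitochondrial respiration (19 of 24, 3 lower; 0.000922), each with the same counts when adjusted over the list alone. Also higher were macrophage (15 of 24, 1 lower; 0.0221) and senescence-associated secretory genes (15 of 21; 0.0236), with the same counts when adjusted over the list alone. Lower were myelinating Schwann cell (18 of 19; 4.64e-05) and sensory neuron (27 of 30, 1 higher; 5.4e-05), with the same counts when adjusted over the list alone. The Schwann cell lineage was lower (12 of 19, 11 when adjusted over the list alone; 0.0028), as was sterol synthesis (16 of 21, 1 higher, also when adjusted over the list alone; 0.0244). The macrophage call was lost without GEM-PNST library 4 (0.0588), the secretory call without library 2 (0.0609) or 4 (0.0513), and the sterol call without library 3 (0.0533).

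Some lists that did not pass held single genes with large changes. The matrix remodelling list had 11 of 29 members higher and 3 lower (camera adjusted p = 0.452), ERK output 7 of 21 higher and 4 lower (0.88), and neural crest regulators 9 of 20 higher and 6 lower (0.995), with the same counts when adjusted over the list alone. Mmp3 and Mmp12, matrix metalloproteinases, rose by 7.55 (SE 1.08) and 6.37 (SE 0.74). Fosl1, an ERK-driven transcription factor, rose by 8.82 (SE 1.02), Msx1, a neural crest factor, by 7.71 (SE 0.74), and Twist1, a factor of mesenchymal cells, by 4.88 (SE 0.61). Ptch1, the hedgehog receptor, fell by 7.54 (SE 0.54). Sox10 had a log2 fold change of -0.51 (adjusted p = 0.674), with an adjusted p of 3.56e-06 without GEM-PNST library 3 and 0.0121 by limma-voom. Cdkn2b was higher by 1.43 (adjusted p = 0.0436), a call lost without GEM-PNST library 1 (0.0548), 3 (0.107) or 4 (0.234) or neurofibroma library 8 (0.0527) or 9 (0.0551), by DESeq2 (0.0534) or limma-voom (0.115), and with the length and GC trend removed (0.904). For Mmp3, Fosl1, Twist1 and Cdkn2b the stages overlapped, with Mmp3 at 0 CPM and Fosl1 at 0.0678 CPM in GEM-PNST library 1.

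Subgroup 2 and subgroup 1 of the paraspinal tumors were compared with the caution that the subgroups may come from these data. By camera the lists of G2 and M phase, S phase and senescence-associated secretory genes were higher in subgroup 2, each with adjusted p = 0.972 with an estimated correlation and none past the threshold by fry. For single genes edgeR called 0, with 2100 at an unadjusted p under 0.05. DESeq2 called 1212 genes, limma-voom 5380, a fit of all 20 libraries 1231 and a fit of the 4 paraspinal libraries alone 4859. Of the G2 and M phase list 25 of 32 members were higher when adjusted over the list alone and 0 over all genes, with a median of 2.2 (camera adjusted p = 5.96e-15; adjusted p = 0.972 with an estimated correlation). Timp1 had a log2 fold change of 5.28 (SE 2.03, adjusted p = 0.361) and Top2a, a topoisomerase of dividing cells, 2.03 (adjusted p = 0.266). Fit by subgroup, 5764 genes differed between subgroup 1 and neurofibroma and 8506 between subgroup 2 and neurofibroma. Between GEM-PNST and subgroup 1 there were 7437, and between GEM-PNST and subgroup 2 there were 2571, or 4405 by DESeq2. These fits take the spread from all 20 libraries, and with only the libraries compared the counts were 1328 and 61.

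The position of each paraspinal library between the other stages followed the subgroups. Subgroup 1 libraries had a Pearson distance of 0.166 and 0.157 from the neurofibroma mean and of 0.24 and 0.276 from the GEM-PNST mean. Subgroup 2 libraries had 0.246 and 0.227 from neurofibroma and 0.145 and 0.152 from GEM-PNST. Over the 2000 most variable genes subgroup 2 library 2 was nearly equidistant, at 0.492 from neurofibroma and 0.479 from GEM-PNST. No test was run on these distances, and the neurofibroma side includes the difference between runs and genotypes.

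**Figure D3:**
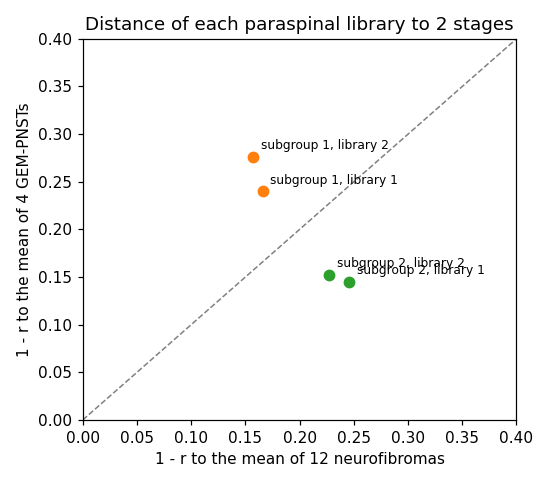
Pearson distance (1 minus r over log2 CPM of the tested genes) of each paraspinal library from the mean of the neurofibroma libraries (x axis) and of the GEM-PNST libraries (y axis). The subgroup 1 libraries lie nearer to neurofibroma, at 0.166 and 0.157, and the subgroup 2 libraries nearer to GEM-PNST, at 0.145 and 0.152.

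A limited set of genes moved the same way at both steps, from neurofibroma to paraspinal and from paraspinal to GEM-PNST. The count was 421, of which 212 rose at each step and 209 fell at each step, while 210 genes rose and then fell, and 53 fell and then rose. Independent lists of these sizes would share 124, 373, 385 and 120. The steps share the 4 paraspinal libraries with opposite sign, so chance errors push towards opposite directions, and the values for independent lists are not what no effect gives. The order against independent lists also turned: 103 genes rose at each step against 123 without GEM-PNST library 2 and 5 against 5.8 without subgroup 1 library 1, 857 fell against 829 with all 20 libraries in 1 fit, and 60 rose and then fell against 58.3 with the replicate number as a block. With the paraspinal libraries split 2 and 2 between the steps, 2 to 6 genes moved the same way, all lower, and 6 to 9 rose and then fell, while the second step called 86 to 131 genes. The 421 became 33 and 66 without subgroup 1 library 1 or 2, 166 and 64 without subgroup 2 library 1 or 2, and 283, 238 and 116 without GEM-PNST library 1, 2 or 4.

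Both comparisons with neurofibroma shared 7889 genes in the same direction, 4038 higher and 3851 lower, with 303 in opposite directions. Independent lists would share 1751 and 1847. Unchanged groups and their shared controls were simulated, all with the neurofibroma spread. They called at most 1 gene, so their overlap of 0 says nothing about this count. The log2 fold changes had a correlation of 0.667 across genes, which are not independent replicates, against 0.25 simulated, and a covariance of 4.11 against 0.05. With the neurofibroma libraries split 6 and 6 between the comparisons, 6695 and 6378 genes were shared for the 2 ways of splitting. These libraries also share the contrast of sequencing runs and of genotype.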

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

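The tests of run, length and GC content, ganglion tissue, cell type share, salivary gland and antigen-presenting cells were chosen, and their bounds set, only after the results were seen, and the counts of other splits were chosen before.

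Among 96 groups of values examined, 4 held a library far from the others of its group, where chance gives about 1 in 20 groups, or 4.8. Paraspinal subgroup 2 library 2 had a total of 24.31 (in units of 1e6 counts), against 18.95 for the nearest paraspinal library. Rn45s, a ribosomal RNA precursor, took 30.74% of the counts of GEM-PNST library 4, against 0.7527% in the nearest library of that stage. Sox10 had 438.4 CPM in GEM-PNST library 3 and 5.666 CPM in the next highest. The matrix remodelling list had a mean log2 CPM of 2.81 in GEM-PNST library 1 and 6.64 in the next lowest.

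Subgroup 2 and subgroup 1 of the paraspinal tumors differed in 6 lists by camera, and the subgroups may have been drawn from these data. Higher in subgroup 2 were the lists of G2 and M phase (median log2 fold change 2.2, adjusted p = 5.96e-15), mitochondrial respiration (0.74, 6.82e-07), S phase (0.96, 1.35e-06), senescence-associated secretory genes (2.64, 0.000463) and macrophages (1.25, 0.0011). Sterol synthesis was lower (-0.74, adjusted p = 0.0112). With an estimated correlation the adjusted p was 0.871 for sterol synthesis and 0.972 for each of the others, and none passed by fry. Without subgroup 1 library 2 the macrophage and sterol lists had adjusted p = 0.0598.

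Many of the tested genes differed between the neurofibroma libraries and those of the other stages, and the splits argue against chance as the reason. Every other split mixed stages within a group, which raises the spread there and lowers the count. The real split was the 1 of 100 splits with as many genes for paraspinal against neurofibroma (9858, highest other 95) and the 1 of 100 for GEM-PNST against neurofibroma (12119, highest other 1649). A gene length and GC trend between libraries is argued against as the whole cause, since 5452 genes were called in the same direction after it was removed. A sequencing run or library batch cannot be told apart from stage, since 0 runs held neurofibroma libraries and libraries of another stage. The disrupted Ink4a/Arf copy was likewise absent from the neurofibroma mice only, so genotype cannot be told apart either. The 33 genes present in every neurofibroma library and at 0 counts in all others, Olfr613 among them, could come from a difference in alignment or annotation, and tumor stage stays open as untested.

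Schwann cell transcripts such as Pmp22 were lower in GEM-PNST than in paraspinal libraries. Over all genes, not Schwann cell genes alone, the splits argue against chance but cannot exclude it. The real split was the 1 of 35 splits with as many genes (1686, highest other 0), the lowest rank that 35 splits allow. Every other split mixed the stages, which raises the spread within a group and lowers the count. The lists of other cell types did not move alike. Their median log2 fold changes, away from the floor, spanned 6.31. The highest was 3.44 for the dendritic cell and MHC class II list and the lowest -2.87 for perineurial cells. These 2 lists were picked as the extremes, which widens the span. The dendritic cell and MHC class II mean was 2.96 log2 CPM in GEM-PNST library 2, below the paraspinal range of 3.68 to 5.21. The values argue against an equal rise of every other cell type, but do not decide whether the share of Schwann cells was lower. The gap between those list means was -0.36 to 1.08 in the paraspinal and 2.12 to 10.37 in the GEM-PNST libraries, and that between macrophage and endothelial cells 0.29 to 1.26 and 1.47 to 3.83, while a loss of Schwann cells together with other nerve cells was not tested. Whether ganglion tissue in the paraspinal dissections carries the Schwann cell transcripts cannot be told, since 0 paraspinal libraries had a sensory neuron mean under 2 log2 CPM. Outside that stage, neurofibroma library 4 had means of 1.15 for sensory neurons, 6.63 for the Schwann cell lineage and 7.26 for myelinating Schwann cells, GEM-PNST library 3 had 0.32, 5.73 and 4.17, and tumor stage stays open as untested.

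GEM-PNST libraries 1 and 3 differed from the other GEM-PNST libraries in transcripts of other cell types. In data outside the tested genes, Bpifa2, a salivary secreted protein, had 28780 CPM in library 3 and at most 0.216 CPM in any other, scaled by library total alone. A candidate explanation is salivary gland tissue in GEM-PNST library 3: 16 of 19 measured salivary genes were highest there, with 4.3% of its counts against at most 0.0553% elsewhere, though Bpifa2, Smr3a, Dcpp1, Car6 and Pip were listed after they were seen to be high. Whether there were antigen-presenting cells added to a tumor library in GEM-PNST library 1 cannot be told, since 1 of 3 lists, fibroblast (1.58 against 6.76 ± 1.02, SD, n = 3), lay more than 2 log2 CPM and more than 2 SD below the other GEM-PNST libraries. The Schwann cell lineage (-0.9 against 2.82 ± 2.61) and endothelial (2.44 against 4.51 ± 1.39) lists lay within 2 SD, and no biological explanation was tested.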

How the results depend on the processing

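Tests without GEM-PNST libraries 1 and 3, without neurofibroma library 4, without Rn45s and Malat1, with the paraspinal libraries split between steps, with the length and GC trend removed or with 1 neurofibroma run were chosen only after the result was seen.

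The count for GEM-PNST against paraspinal (1686) was 4711 with DESeq2, 2714 with limma-voom, 6631 with all 20 libraries in 1 fit and 61 against subgroup 2 alone, and 507 to 2304 with single libraries left out. For the both-step genes (421) it was 1711 with DESeq2, 2323 with all 20 libraries, 33 to 614 with single libraries left out, and 6, 3, 2 and 3 with the paraspinal libraries split 2 and 2. Between subgroups (0 by edgeR, 2100 at an unadjusted p under 0.05) it was 1212 with DESeq2, 5380 with limma-voom, 1231 with all 20 libraries and 4859 with the 4 paraspinal libraries only. GEM-PNST against subgroup 2 gave 4405 genes with DESeq2. Over the 2000 most variable genes the subgroup 1 libraries' distance to GEM-PNST minus that to neurofibroma was 0.187 and 0.361, against 0.074 and 0.119, and for subgroup 2 library 2 it was -0.013, against -0.075, nearly equidistant. The cause was not tested.

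With the number as a replicate block the counts were 2762 for paraspinal against neurofibroma, 840 for GEM-PNST against paraspinal, 7204 for GEM-PNST against neurofibroma and 47 for both steps. Of 14 same-numbered pairs 6 had a correlation over 0.1 and 1 had a correlation below -0.1 (range -0.259 to 0.168). Differently numbered pairs were not compared, so these values do not decide whether the numbers pair the samples.

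Log2 fold changes that reversed in paraspinal against neurofibroma were those of Sox10 (-0.46) and Foxd3 (-0.59) with the length and GC trend removed and Timp1 (-0.05) with subgroup 1 alone. In GEM-PNST against paraspinal Cdkn2b (-0.29, not called) had 0.57 with subgroup 1 alone, 0.03 without subgroup 2 library 2 and 0.1 without GEM-PNST library 2, in a range of -0.79 to 0.1 over single libraries left out. The cause was not tested.

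For 57 genes of paraspinal against neurofibroma 1092 of 1140 values kept direction and call, with 45 weaker. For 83 of GEM-PNST against paraspinal 1269 of 1655 did, with 356 weaker and 27 stronger, and for 70 of GEM-PNST against neurofibroma 1292 of 1323, with 26 weaker and 5 stronger. Of 29 list calls none passed with an estimated correlation and 19 passed by fry. By depth, a gene at 0 counts could not be told from 0.303 CPM or less in the shallowest library.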

Other observations

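All values here were picked out only after they were seen, and no test was run on them.

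Neurofibroma library 4 had a sensory neuron list mean of 1.15 log2 CPM, against 6.2 to 8.63 in the other neurofibroma libraries. GEM-PNST library 1 had 39990 CPM of Cd74 and 34570 CPM of H2-Ab1, both of MHC class II presentation. Pdgfra, a receptor of fibroblasts and other mesenchymal cells, had 0.0678, 551.1, 75.32 and 635.3 CPM in GEM-PNST libraries 1 to 4. Hmga2, a chromatin protein of embryonic cells, had 0.0678, 636.9, 26.32 and 421.6 CPM in the same libraries. Malat1, a nuclear long noncoding RNA, took 2.52% to 3.578% of the counts in neurofibroma libraries and 0.0163% to 0.09043% in the others.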
